A study of Mus musculus with 16 samples.

How the data were processed

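RNA from the livers of male PPARβ/δ knockout mice and wild-type mice, each either fed or fasted for 24 h, was measured on Affymetrix whole-transcript arrays, 1 array per mouse. The 16 arrays form 4 groups: 4 wild-type fed, 5 wild-type fasted, 4 knockout fed and 3 knockout fasted mice. The labels call the replicates biological replicates, so each stands for a separate mouse, and none of these arrays was left out here. The series text gives 4 to 5 mice per group, but the knockout fasted group has 3 arrays. Whether an array was removed before deposit is not known. The array's genome build and the version of the software that made the values are not given in the sources used here.

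The deposited values are normalized probe set intensities, made by the authors with RMA per the submitters' processing notes. They were on a linear scale, with array medians of intensity between 8.08 and 8.61, and log2 was taken here before any test. The 35519 probe sets held no missing value and no identical pair of arrays. Of these, 21780 were paired with 1 gene symbol, 1605 with several and 12134 with none. Probe sets with 1 symbol were used, and 998 genes had more than 1 probe set, of which the probe set with the highest mean over all arrays stood for the gene, which left 19935 genes. The number of arrays limits the precision of every value.

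Differential expression was tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, without an intensity trend). All arrays entered 1 fit of 4 group means, with 12 residual and 4.55 prior degrees of freedom. From it came 6 contrasts: knockout minus wild-type in fed mice, the same in fasted mice, fasted minus fed in each genotype, the difference between the fasting responses (the interaction), and the mean of the knockout effects in fed and fasted mice. Tests were two-sided, and p was adjusted by the Benjamini-Hochberg method over the genes tested within each contrast. A gene counted as changed at an adjusted p under 0.05. Log2 fold changes are printed with the standard error of the limma fit.

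The contrasts, tests, gene lists, most alternatives and the rule for which genes to name were chosen before the data were examined. The rule named Ppard, Ppara and Pparg in every contrast. It added the 8 largest rises and the 8 largest falls among changed genes for which every array of one group lay above every array of the other; the interaction took up to 5 each way without that condition. It also added up to 4 changed members of each called gene list in the direction of the list and up to 2 in the other direction. Predicted and unnamed loci, receptor families of smell, small RNAs and antigen receptor segments were left out of the largest rises and falls. In all, 165 genes met it. Genes outside the rule are said to have been chosen after their values were seen.

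The 32 gene lists were written from general knowledge of liver biology, 21 for pathways and functions and 11 for cell types, and no list was taken from these samples. They were tested with limma's camera at its preset inter-gene correlation of 0.01, two-sided, with p adjusted over the lists within a contrast. Beside it stand camera with a correlation estimated from the data, and fry, which tests whether a list's genes move on balance one way. Members that passed the gene test were counted after adjustment over all genes and also adjusted over the list alone. A list's score on an array is the mean over its measured genes of the log2 value minus that gene's mean over all arrays.

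Genes near Ppard were compared with all others by Fisher's exact test, two-sided. The neighbours were the 150 tested genes on each side along the chromosome, by gene order in the GRCm38.p6 assembly, used for names and order only. The alternatives tried were quantile normalization, centring each array on the common median, leaving out dim genes (mean under the 40th percentile, log2 2.79), all probe sets, the median of a gene's probe sets, an intensity trend with robust variance, array weights, the replicate number as a block, a fit of the 2 groups alone, other neighbourhood sizes, an estimated correlation for the lists, and leaving out each array in turn. Leaving out knockout fed mice 1 and 4 together was added after seeing the data.

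The fits were tested on simulated data of the same shape, with 50 changed genes at each of several sizes per contrast. At a log2 size of 1, the share recovered was 96% for knockout in fed mice, 90% for knockout in fasted mice, 96% for fasting in wild-type mice, 94% for fasting in knockout mice, 82% for the interaction and 98% for the mean knockout effect. At a log2 size of 0.5 these shares were 68%, 74%, 52%, 56%, 36% and 86%. Of the genes called, 2.67%, 4.71%, 7.45%, 5.46%, 3.64% and 6.80% had not been changed, in the same order. With a shift of 0.4 put into the interferon response list, camera called that list and no other of the 32. Genes were simulated independently of each other. The simulation therefore does not show how often lists of genes that vary together are called falsely.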

Results

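Liver RNA was measured in 16 male mice of a mixed Sv129/C57Bl/6 background, in a 2 by 2 layout of genotype (wild-type or PPARβ/δ knockout) and feeding (fed, or fasted for 24 h). PPARβ/δ, encoded by Ppard, is a nuclear receptor for fatty acids. The groups held 4 wild-type fed, 5 wild-type fasted, 4 knockout fed and 3 knockout fasted mice, and 19935 genes were tested. The first principal component carried 34% of the variance of the 11961 brighter genes and separated fasted from fed mice, with scores of 7.64 and above in every fasted mouse and -12.7 and below in every fed mouse. Knockout fasted mice scored 7.64 to 11 on it, below the 18.91 to 25.03 of wild-type fasted mice. The second carried 13% and put every wild-type fed mouse, at -24.06 to -8.48, below every knockout fed mouse, at 4.87 and above. Fasted mice overlapped on the second component, at -2.75 to 2.75 in wild-type and -6.71 to 5.65 in knockout mice. On it, knockout fed mice 1 and 4 stood apart from all others, with scores of 19.6 and 19.7. The same mice had the highest scores of the acute phase list, 0.82 and 1.36, against 0.21 and -0.37 in knockout fed mice 3 and 2 and -0.46 to -0.24 in wild-type fed mice.

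**Figure D1:**
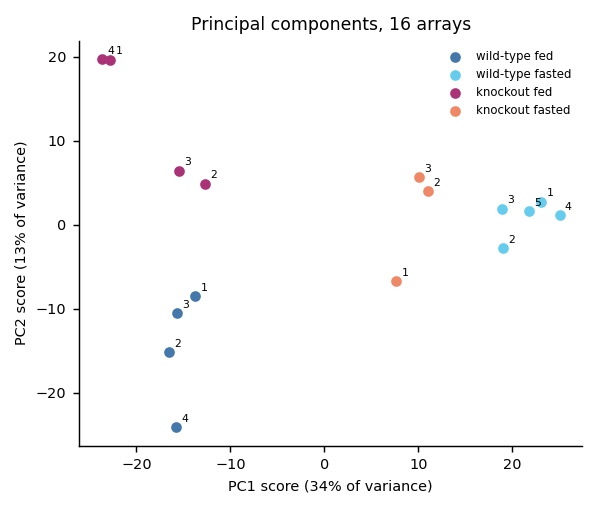
Scores of the 16 arrays on the first and second principal component of log2 intensity, coloured by group and numbered by replicate. Fasted and fed mice part on the first component (34% of the variance), and knockout fed mice 1 and 4 lie apart on the second (13%).

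Ppard itself gave log2 intensities of 4.78, 5.50, 5.31 and 4.83 in wild-type fed mice and 4.62, 4.40, 4.54, 4.67 and 4.58 in wild-type fasted mice. Knockout fed mice gave 5.00, 4.50, 4.45 and 4.89, and knockout fasted mice 4.50, 4.36 and 4.58. In wild-type mice Ppard fell with fasting, from a mean of 5.11 to 4.56, near the 4.48 of knockout fasted mice. Its fasting change in the fit without knockout fed mice 1 and 4 was -0.54 in wild-type mice (adjusted p = 0.0139). The knockout minus wild-type difference was -0.39 ± 0.15 in fed mice (adjusted p = 0.266) and -0.08 ± 0.16 in fasted mice (adjusted p = 0.908), and neither passed; without knockout fed mice 1 and 4 the fed value was -0.63 (adjusted p = 0.2). Which part of the gene was deleted is not given in the sources used here, so the value checks nothing about the genotype. Ppara, the receptor of the fasting response, rose with fasting by 1.00 ± 0.17 in wild-type mice (adjusted p = 0.00125) and by 0.90 ± 0.20 in knockout mice (adjusted p = 0.0154). It did not pass between genotypes (fed -0.23 ± 0.18, adjusted p = 0.62). Its fasting value in knockout mice was 0.58 without knockout fed mice 1 and 4 (adjusted p = 0.122). Pparg, the adipocyte receptor, was lower in knockout mice in the mean of both feeding states, by -0.36 ± 0.08 (adjusted p = 0.0292), and by -0.31 without those mice (adjusted p = 0.155).

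The first comparison asked what a fast of 24 h did to the liver of wild-type mice (5 fasted against 4 fed). The largest rise measured was that of Cyp4a14, a fatty acid omega-hydroxylase and PPAR target, by 7.20 ± 0.61 on the log2 scale (adjusted p = 1.47e-06). In 2 of the 4 fed mice its log2 intensity was 2.81, near the limit of 2.79 under which genes were taken as dim, so the value is a lower bound. The pantetheinase gene Vnn1, another target, rose by 3.02 ± 0.47 (adjusted p = 0.000577). Genes that make cholesterol and fatty acids fell, among them Sqle (-2.10 ± 0.31, adjusted p = 0.00042) and Fasn, the fatty acid synthase (-1.85 ± 0.15, adjusted p = 1.09e-06). The lysolipid transporter Mfsd2a rose by 4.01 ± 0.46, the metallothionein Mt1 by 3.84 ± 0.82 and Rab30 by 3.05 ± 0.27. The largest fall was that of Hsd3b5, a steroid dehydrogenase of male liver, at -3.70 ± 0.25 (adjusted p = 2.39e-07). In all, 658 genes rose and 1180 fell, and 217 of these 1838 changed at least 2-fold. For 1503 of them (81.8%) every fasted mouse lay on the same side of every fed mouse. Genes called with so few arrays tend to have groups apart, so such shares, here and in the comparisons below, add no separate support.

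Of 44 measured PPAR target and peroxisomal genes, 29 rose and 1 fell (34 and 1 adjusted over the list alone), with a mean log2 change of 1.25 (camera adjusted p = 1.95e-28). Cyp4a10 rose by 4.93 ± 0.37 and Cyp4a31 by 5.72 ± 0.47; these are near-identical genes that can share probe signal, so their values are not separate. Within the list, the acyl-CoA thioesterase Acot3 rose by 2.33 ± 0.24 (a lower bound, from a dim mean of 2.78 in fed mice), and the fatty acid transporter Cd36 was its 1 fall, by -0.83 ± 0.18. Of 20 cholesterol biosynthesis genes none rose and 17 fell (18 adjusted over the list alone), mean -1.19 (adjusted p = 1.29e-25), with Nsdhl at -2.01 ± 0.18, Idi1 at -1.94 ± 0.23 and Hmgcs1 at -1.87 ± 0.18. Both calls held with an estimated correlation (adjusted p = 0.0184 for each), as did that of the female-biased liver genes, of which 8 of 25 rose and none fell (10 adjusted over the list alone; mean 0.54, adjusted p = 6.06e-05, and 0.0164 with an estimated correlation). Examples are Cyp17a1 at 2.79 ± 0.61 and the flavin monooxygenase gene Fmo2 at 1.52 ± 0.28. Of 22 male-biased liver genes, 12 fell and 1 rose (17 and 1 adjusted over the list alone), mean -0.82, adjusted p = 6.72e-12, and adjusted p = 0.102 with an estimated correlation.

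Mitochondrial fatty acid oxidation and ketogenesis rose in 17 of 25 genes and fell in 1 (18 and 1 adjusted over the list alone). The mean was 0.53 (adjusted p = 6.39e-15, and adjusted p = 0.102 with an estimated correlation). Cpt1a, which admits long-chain fatty acids to mitochondria, rose by 1.39 ± 0.16 and the carnitine carrier Slc25a20 by 1.13 ± 0.08. Of 32 genes of fatty acid and triglyceride synthesis, 14 fell and 6 rose (16 and 6 adjusted over the list alone), mean -0.44, adjusted p = 5.84e-06, and adjusted p = 0.102 with an estimated correlation. Scd1 fell by -1.78 ± 0.32 and the regulator Srebf1 by -1.64 ± 0.20, while Lpin1 rose by 1.83 ± 0.53. Gluconeogenesis and the fasting hormone response rose in 11 of 30 genes and fell in 1 (14 and 1 adjusted over the list alone; mean 0.39, adjusted p = 6.01e-06, and adjusted p = 0.139 with an estimated correlation). Its members include Fkbp5, a glucocorticoid-induced gene, at 2.52 ± 0.29, and Pck1 at 0.88 ± 0.14. The fasting hormone gene Fgf21 rose by 1.56 ± 0.29.

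Interferon response genes fell in 12 of 39 and rose in none (21 adjusted over the list alone), mean -0.41, adjusted p = 8.86e-12, and adjusted p = 0.111 with an estimated correlation; Bst2 fell by -1.23 ± 0.14. Circadian clock genes changed both ways, 8 of 21 up and 4 down (12 and 4 adjusted over the list alone; mean 0.53, adjusted p = 0.00129, and adjusted p = 0.254 with an estimated correlation). The clock output gene Dbp rose by 2.49 ± 0.40 and Per1 by 1.94 ± 0.16, and Arntl fell by -1.52 ± 0.18. Of 35 endoplasmic reticulum and heat shock stress genes, 10 fell and 3 rose (13 and 3 adjusted over the list alone; mean -0.24, adjusted p = 0.000181, and adjusted p = 0.55 with an estimated correlation, or 0.049 in the fit without knockout fed mice 1 and 4). The chaperone Pdia6 fell by -1.32 ± 0.11. Of 34 genes of glycolysis, pentose phosphate and glycogen metabolism, 11 fell and 3 rose (14 and 5 adjusted over the list alone; mean -0.21, adjusted p = 0.000305, and adjusted p = 0.102 with an estimated correlation). Lipoprotein metabolism rose in 9 of 33 genes and fell in 5 (13 and 5 adjusted over the list alone; mean 0.12, adjusted p = 0.0127, and adjusted p = 0.295 with an estimated correlation). Complement and coagulation fell in 9 of 43 and rose in 1 (11 and 3 adjusted over the list alone; mean -0.14, adjusted p = 0.0028, and adjusted p = 0.55 with an estimated correlation).

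Among cell type markers, stellate cell and fibroblast genes (2 of 26 fell, mean -0.21, adjusted p = 0.016) and sinusoidal endothelial genes (3 of 24 fell, mean -0.13, adjusted p = 0.0279) were called lower. Pancreas markers (none of 17 passed, mean 0.41, adjusted p = 0.016) and T and NK cell markers (none of 24 passed, mean 0.10, adjusted p = 0.0214) were called higher. With an estimated correlation these had adjusted p = 0.55, adjusted p = 0.55, adjusted p = 0.706 and adjusted p = 0.524. Leaving out single mice ended each of these calls. Pancreas markers scored 1.56 in wild-type fasted mouse 5 and -0.19 to 0.19 in the other 4 fasted mice, and without it the mean was 0.09 (adjusted p = 0.185), while that of T and NK cell markers was 0.07 (adjusted p = 0.137). The T and NK call was also lost without wild-type fed mouse 1 (mean 0.089, adjusted p = 0.0513). Without wild-type fed mouse 4 the stellate mean was -0.09 (adjusted p = 0.253), and it was -0.18 without wild-type fasted mouse 2 (adjusted p = 0.0918); the endothelial call was lost without any of 4 single mice. Among the endothelial genes that fell, Clec4g was at -0.85, but its other probe set gave 0.06 (limma adjusted p = 0.817). Cd36, another of them, is also in the PPAR target list. The call count of 1838 became 1199 without wild-type fed mouse 3.

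The same comparison in knockout mice (3 fasted against 4 fed) changed 732 genes, 373 up and 359 down, 124 of them at least 2-fold. Cyp4a14 rose by 4.93 ± 0.69 (30.6-fold, adjusted p = 0.000794), the acyl-CoA thioesterase Acot1 by 2.91 ± 0.51 (adjusted p = 0.00439) and Rab30 by 2.74 ± 0.31 (adjusted p = 0.000104). Thrsp, a lipogenic gene, fell by -3.15 ± 0.43 (adjusted p = 0.000555), Fasn by -2.48 ± 0.17 (adjusted p = 7.65e-07) and Sqle by -2.34 ± 0.36 (adjusted p = 0.00143). For 714 of the 732 (97.5%) every fasted mouse lay on the same side of every fed mouse.

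Cholesterol biosynthesis fell in 17 of 20 genes and rose in none (17 adjusted over the list alone), mean -1.37, adjusted p = 6.91e-35, and 0.00798 with an estimated correlation; Fdps fell by -2.14 ± 0.18. Of 44 PPAR target and peroxisomal genes, 21 rose and none fell (31 adjusted over the list alone), mean 0.98, adjusted p = 5.51e-29, and 0.0168 with an estimated correlation. Mitochondrial fatty acid oxidation rose in 12 of 25 genes (18 adjusted over the list alone; mean 0.49, adjusted p = 8.01e-22, and 0.037 with an estimated correlation, or 0.0883 without knockout fed mice 1 and 4), with Cpt1a at 1.27 ± 0.19. Fatty acid and triglyceride synthesis fell in 13 of 32 genes and rose in 4 (18 and 6 adjusted over the list alone), mean -0.65, adjusted p = 1.13e-10, and 0.0168 with an estimated correlation. Acss2, which makes acetyl-CoA from acetate, fell by -1.66 ± 0.13. Interferon response genes fell in 21 of 39 and rose in none (32 adjusted over the list alone), mean -0.67, adjusted p = 6.45e-27, and 0.0168 with an estimated correlation. Examples are Dhx58 at -1.04 ± 0.18 and Rtp4 at -0.99 ± 0.17. Female-biased genes rose in 6 of 25 (7 adjusted over the list alone), mean 0.39, adjusted p = 3.99e-05, and 0.00798 with an estimated correlation.

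Several other lists were called at the preset correlation. Gluconeogenesis and the fasting hormone response rose in 5 of 30 genes (9 adjusted over the list alone; mean 0.31, adjusted p = 1.51e-06, and adjusted p = 0.141 with an estimated correlation). Amino acid catabolism and the urea cycle rose in 4 of 43 (11 up and 1 down adjusted over the list alone; mean 0.15, adjusted p = 2.15e-05, and adjusted p = 0.308 with an estimated correlation), with the urea cycle gene Asl at 0.89 ± 0.14. Kupffer cell and macrophage markers fell in 2 of 34 (8 adjusted over the list alone; mean -0.25, adjusted p = 1.12e-05, and adjusted p = 0.311 with an estimated correlation). Clock genes rose in 2 of 21 (5 adjusted over the list alone; mean 0.25, adjusted p = 0.00327, and adjusted p = 0.314 with an estimated correlation). Lipoprotein genes (3 of 33 up and 2 down, mean 0.12, adjusted p = 0.0175) and glycolysis genes (6 of 34 down, mean -0.13, adjusted p = 0.0433) had adjusted p = 0.314 and adjusted p = 0.352 with an estimated correlation. The lipoprotein mean was 0.06 without knockout fasted mouse 1 (adjusted p = 0.162) and 0.09 without knockout fed mouse 2 (adjusted p = 0.0744). The glycolysis mean was -0.14 without knockout fed mice 1 and 4 (adjusted p = 0.0615) and -0.08 without knockout fasted mouse 2 (adjusted p = 0.2). Xenobiotic metabolism rose in 9 of 65 genes and fell in 2, mean 0.06, adjusted p = 0.0332, with the nuclear receptor Nr1i3 at 1.51 ± 0.22. Bile acid synthesis and transport rose in 4 of 33 and fell in 1, mean 0.12, adjusted p = 0.0403, with the bile acid hydroxylase Cyp8b1 at 1.12 ± 0.20. With an estimated correlation both were lost, at adjusted p = 0.581 and adjusted p = 0.352. Both calls were lost as well without knockout fed mice 1 and 4. Single mice ended them too, any of 3 for the xenobiotic list and any of 5 for the bile acid list. The xenobiotic mean was 0.017 without knockout fed mouse 4 (adjusted p = 0.138) and 0.117 without knockout fed mouse 3 (adjusted p = 0.00257). Without mice 1 and 4 the xenobiotic mean turned to -0.01 (3 up and 2 down, adjusted p = 0.404), the bile acid mean was 0.02 with 1 gene up (adjusted p = 0.492), and Cyp8b1 was 0.95 (adjusted p = 0.0741).

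Other lists whose calls also depended on knockout fed mice 1 and 4 were acute phase (1 of 38 up and 2 down, mean -0.65, adjusted p = 9.53e-06), endoplasmic reticulum and heat shock stress (1 of 35 up and 4 down, mean -0.36, adjusted p = 1.51e-06) and neutrophil markers (none of 18, mean -0.27, adjusted p = 0.0187). With an estimated correlation they had adjusted p = 0.383, adjusted p = 0.352 and adjusted p = 0.314. Without these 2 mice the means were -0.06, 0.01 and -0.09, and none was called. Immediate early genes (none of 27, mean -0.39, adjusted p = 0.0194, and adjusted p = 0.581 with an estimated correlation) depended on mouse 1 alone of these 2, with a score of 1.34 against 0.09 in mouse 4. Their mean was -0.06 without knockout fed mouse 1 (adjusted p = 0.78), -0.30 without knockout fasted mouse 2 (adjusted p = 0.102) and -0.635 without knockout fed mouse 2 (adjusted p = 3.22e-05). The acute phase gene Saa1 fell by -3.81 ± 0.95 with all arrays (adjusted p = 0.0324) and by -1.93 without knockout fed mice 1 and 4 (adjusted p = 0.319). The whole count became 218 without them, with 37 of 71 named genes kept, and 401 in a fit of these 2 groups alone.

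Fasting changed many of the same genes in both genotypes. Of the 19935 genes, 224 rose in both where 12.3 would be expected by chance, and 246 fell in both where 21.3 would be expected; 2 changed in opposite directions. The comparisons share no array. Across all genes the log2 changes correlated with r = 0.493 (across genes, which are not independent replicates). Of the 1838 genes changed in wild-type mice, 1554 (84.5%) had the same sign in knockout mice, with a median ratio of knockout to wild-type change of 0.511. Of the 732 changed in knockout mice, 682 (93.2%) had the same sign in wild-type mice, with a median ratio of wild-type to knockout change of 0.78. Genes picked for a change in one group tend to give smaller values in another. Without knockout fed mice 1 and 4 the shared genes numbered 182.

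**Figure D2:**
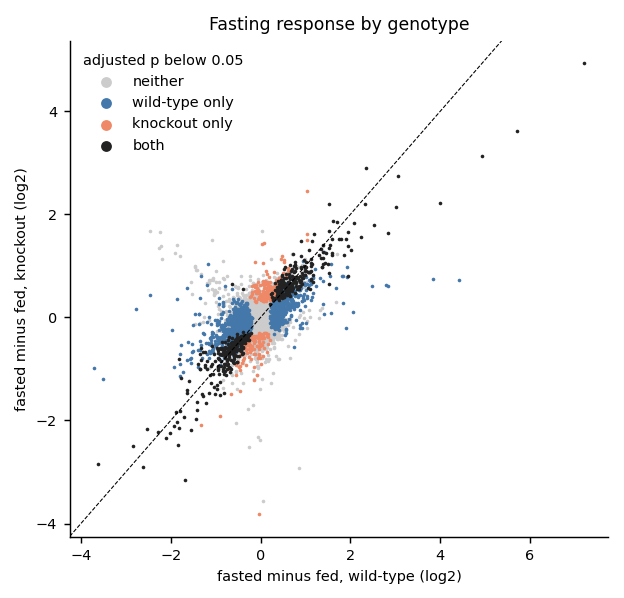
Log2 change with fasting in wild-type mice (horizontal) and in knockout mice (vertical) for 19935 genes, coloured by where the adjusted p was below 0.05. The dashed line marks equal change; 470 genes changed the same way in both.

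The interaction asked which genes responded to fasting differently in the 2 genotypes (all 4 groups). Hsd3b5 fell with fasting in wild-type mice by -3.70 ± 0.25, and its value in knockout mice was -0.99 ± 0.29 (adjusted p = 0.0689). The difference was 2.72 ± 0.38 (adjusted p = 0.0284). Tc2n passed too (adjusted p = 0.0284), but its means were dim in all 4 groups (1.92 to 2.51), so no size is given. These were the only calls, both higher in knockout mice, with 2441 genes at an unadjusted p under 0.05 in limma. Without knockout fed mice 1 and 4 neither passed (Hsd3b5 at 2.50, adjusted p = 0.168, and Tc2n with adjusted p = 0.177). Of 100 splits of the arrays, the real one included, 5 gave as many calls. The adjusted p of the interaction was 0.895 for Ppara.

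Male-biased liver genes differed between the fasting responses by a mean of 0.77 over 22 genes (1 passed, 9 adjusted over the list alone; adjusted p = 6.44e-12, and adjusted p = 0.426 with an estimated correlation). Their mean fasting change was -0.82 in wild-type mice and -0.05 in knockout mice, the latter not called (adjusted p = 0.765). The mean rise of PPAR target genes was smaller in knockout mice, with a difference of -0.27 (none of 44 passed, 1 up and 4 down adjusted over the list alone; adjusted p = 0.00385), and the mean fall of interferon genes was larger, with a difference of -0.26 (none of 39 passed, 3 down adjusted over the list alone; adjusted p = 0.00385). Both had adjusted p = 0.713 with an estimated correlation. The mean PPAR target score was -0.668 in wild-type fed and -0.451 in knockout fed mice. It was 0.579 in wild-type fasted and 0.527 in knockout fasted mice. On this list the genotype means thus lay further apart in fed than in fasted mice. No single gene passed in the other 8 called lists. Means were -0.90 for acute phase (adjusted p = 9.18e-05), -0.38 for neutrophil markers, 0.19 for sinusoidal endothelial markers and -0.55 for pancreas markers (adjusted p = 0.00342 for these 3). They were 0.10 for amino acid catabolism and -0.21 for Kupffer cell and macrophage markers (adjusted p = 0.00388 for both), 0.25 for stellate cell markers (adjusted p = 0.00392) and 0.11 for complement and coagulation (adjusted p = 0.0283). With an estimated correlation complement had adjusted p = 0.773 and the other 7 adjusted p = 0.713. Without knockout fed mice 1 and 4 the acute phase mean was -0.32 (adjusted p = 0.212), the neutrophil mean -0.20 (adjusted p = 0.12), and endoplasmic reticulum and heat shock stress genes turned from -0.13 to 0.25. Without wild-type fasted mouse 5 the pancreas mean was -0.23 (adjusted p = 0.00142), and without wild-type fasted mouse 1 that of PPAR targets was -0.16 (adjusted p = 0.0421). Calls ended for interferon (-0.185, adjusted p = 0.0934) and macrophage genes (-0.15, adjusted p = 0.0677) without wild-type fasted mouse 3, for stellate cell markers without wild-type fed mouse 4 (0.13, adjusted p = 0.10), and for complement without any of 5 single mice, as at 0.06 without knockout fed mouse 2 (adjusted p = 0.261).

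**Figure D3:**
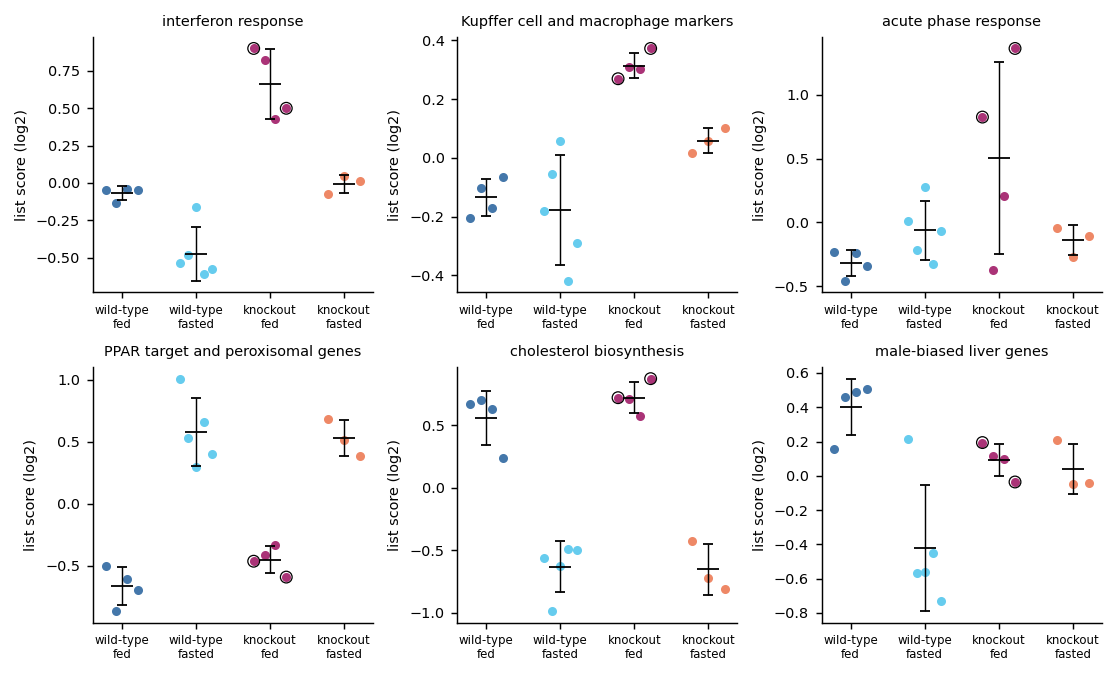
Scores of 6 gene lists per array (mean log2 value of the list's genes, each centred on its mean over 16 arrays), with group means and SD as bars; rings mark knockout fed mice 1 and 4. The interferon score of every knockout mouse lies above that of every wild-type mouse in the same feeding state.

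The next comparison asked what the knockout changed in fed mice (4 against 4). Interferon response genes were higher: Oas1a, an antiviral enzyme, rose by 1.48 ± 0.17 (2.80-fold, adjusted p = 0.00203), the guanylate-binding protein gene Gbp3 by 1.44 ± 0.20 (adjusted p = 0.00361), Usp18 by 1.34 ± 0.26 (adjusted p = 0.0196) and Ifit1 by 1.27 ± 0.23 (adjusted p = 0.016). Macrophage genes were higher too, with the Kupffer cell lectin Clec4f at 0.88 ± 0.11 (adjusted p = 0.00203) and Mpeg1 at 1.50 ± 0.23 (adjusted p = 0.00544). Among metabolic genes, Acnat2, an acyl-CoA acyltransferase, rose by 2.42 ± 0.29 (adjusted p = 0.00203). Hsd3b2 fell by -2.65 ± 0.40 (adjusted p = 0.0052) and Hsd3b3 rose by 1.64 ± 0.22 (adjusted p = 0.00208), near-identical steroid dehydrogenase genes whose probes can share signal. Nat8f5 fell by -1.70 ± 0.29 (a lower bound of the size, to a dim mean of 2.55), the ectonucleotidase gene Nt5e by -1.34 ± 0.22 and the complement inhibitor Cd59a by -1.07 ± 0.15. In all, 90 genes rose and 45 fell, 31 of the 135 by at least 2-fold, and for 127 (94.1%) the 2 groups of arrays did not overlap.

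Of 39 interferon response genes, 17 rose and none fell (33 adjusted over the list alone), mean 0.73, adjusted p = 2.70e-36, and 0.0214 with an estimated correlation. Every knockout fed mouse scored above every wild-type fed mouse on this list, and without knockout fed mice 1 and 4 the mean was 0.70, with 9 genes up (adjusted p = 0.063 with an estimated correlation). Kupffer cell and macrophage markers rose in 9 of 34 and fell in none (19 adjusted over the list alone), mean 0.45, adjusted p = 7.51e-19, and adjusted p = 0.0518 with an estimated correlation. Fcgr1 rose by 0.89 ± 0.13 and the oxidase subunit Cybb by 0.89 ± 0.17; without those mice the mean was 0.44. MHC class II and antigen presentation rose in 2 of 22 (3 adjusted over the list alone; mean 0.14, adjusted p = 0.00664, and adjusted p = 0.404 with an estimated correlation), namely Ctss at 0.76 ± 0.16 and Cd86 at 0.55 ± 0.10; without those mice neither passed and the mean was 0.09 (adjusted p = 0.101). PPAR target genes rose in 2 of 44 and fell in none (4 adjusted over the list alone; mean 0.22, adjusted p = 0.0336, and adjusted p = 0.716 with an estimated correlation), the pair being Cyp4a31 at 2.47 ± 0.49 and Cyp4a10 at 2.07 ± 0.39. The call was lost without any of 3 single mice, as without wild-type fed mouse 2 (mean 0.15, adjusted p = 0.178).

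Male-biased genes fell in 3 of 22 (4 down and 1 up adjusted over the list alone; mean -0.31, adjusted p = 0.00122, and adjusted p = 0.485 with an estimated correlation), with the urinary protein gene Mup21 at -1.46 ± 0.30. Mitochondrial fatty acid oxidation fell in 1 of 25 genes (5 adjusted over the list alone; mean -0.09, adjusted p = 0.00672, and adjusted p = 0.716 with an estimated correlation), that of the medium-chain dehydrogenase Acadm at -0.39 ± 0.08. The mean was -0.05 with no gene down without knockout fed mice 1 and 4 (adjusted p = 0.228), -0.05 without wild-type fed mouse 1 (adjusted p = 0.0739) and -0.06 without knockout fed mouse 4 alone (adjusted p = 0.0936). Acadm was -0.30 without mice 1 and 4 (adjusted p = 0.294). Cell cycle genes rose in 1 of 37, Ccnd1 at 1.08 ± 0.21, with a mean of 0.11 (adjusted p = 0.00403, and adjusted p = 0.398 with an estimated correlation). Small shifts were also called for T and NK cell markers (mean 0.10, adjusted p = 0.00403), glycolysis (mean -0.10, adjusted p = 0.0246), amino acid catabolism (mean -0.06, adjusted p = 0.0336) and cholesterol biosynthesis (mean 0.16, adjusted p = 0.0336). With an estimated correlation these had adjusted p = 0.404, adjusted p = 0.404, adjusted p = 0.716 and adjusted p = 0.716. The last 3 were not called without knockout fed mice 1 and 4, at -0.09 (adjusted p = 0.105), -0.08 (adjusted p = 0.101) and 0.08 (adjusted p = 0.364). Single mice ended these calls too: any of 3 for glycolysis (adjusted p = 0.063 to 0.121), any of 4 for amino acid catabolism (adjusted p = 0.14 to 0.221) and any of 3 for cholesterol biosynthesis. The cholesterol mean was 0.05 without wild-type fed mouse 4 (adjusted p = 0.558), the lowest of its group. In the amino acid list 1 of 43 genes fell, Bckdhb at -0.66 ± 0.10.

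Acute phase genes (none of 38 passed, 15 up adjusted over the list alone; mean 0.83, adjusted p = 8.39e-12), endoplasmic reticulum and heat shock stress genes (none of 35, 6 up adjusted over the list alone; mean 0.42, adjusted p = 2.87e-10) and neutrophil markers (none of 18, 2 up adjusted over the list alone; mean 0.30, adjusted p = 0.00184) moved with knockout fed mice 1 and 4. With an estimated correlation they had adjusted p = 0.401, adjusted p = 0.401 and adjusted p = 0.398. Without these mice the means were 0.24, 0.04 and 0.12, and acute phase stayed called (adjusted p = 0.0125), the others not. Immediate early genes (none of 27; mean 0.40, adjusted p = 0.00664, and adjusted p = 0.716 with an estimated correlation) had a mean of 0.07 without knockout fed mouse 1 (adjusted p = 0.508), of 0.295 without wild-type fed mouse 1 (adjusted p = 0.0739) and of 0.64 without knockout fed mouse 2 (adjusted p = 7.84e-07). The whole count became 51 without knockout fed mice 1 and 4, with 15 of 27 named genes kept. Those lost include Ifit1 (1.42, adjusted p = 0.0531), Hsd3b2 (-2.35, adjusted p = 0.0649) and Nat8f5 (adjusted p = 0.0575). Nt5e (-1.19, adjusted p = 0.102) and Ccnd1 (1.14, adjusted p = 0.119) did not pass without those mice either. Serpina12 was -1.88 ± 0.40 with all arrays (adjusted p = 0.0389) and -1.25 without them (adjusted p = 0.36), and the haem oxygenase gene Hmox1 1.29 ± 0.27 (adjusted p = 0.0389) and 0.72 (adjusted p = 0.359). Leaving out single arrays moved the count between 59 and 274, and a fit of these 2 groups alone gave 76.

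**Figure D4:**
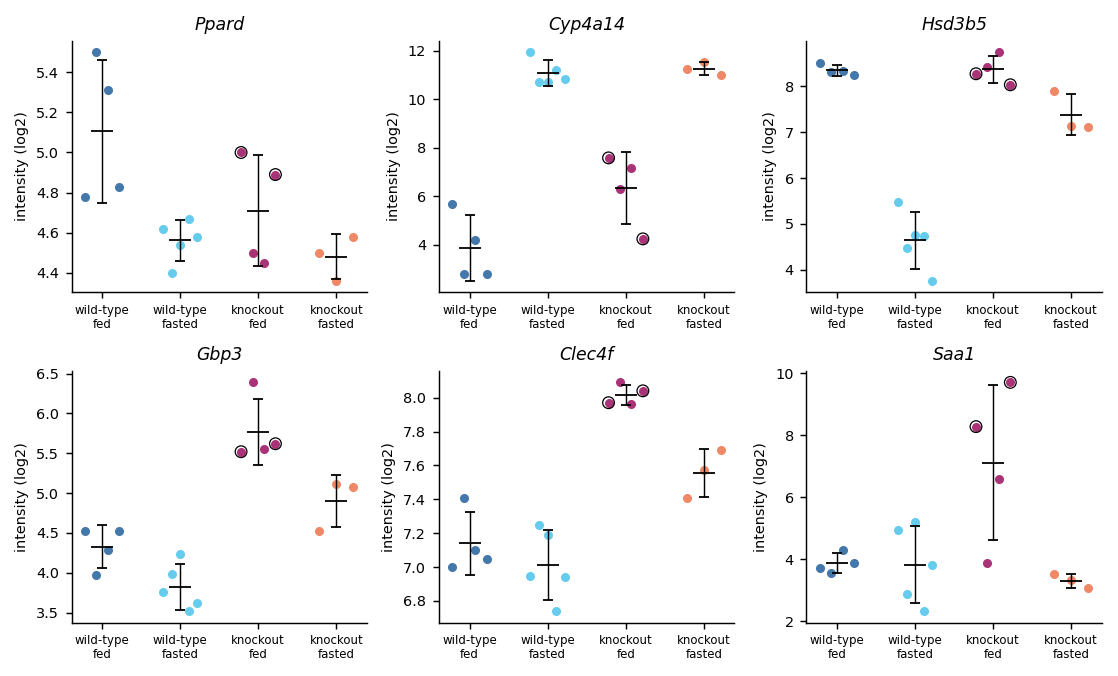
Log2 intensity of 6 genes per array, with group means and SD as bars; rings mark knockout fed mice 1 and 4. Ppard did not pass between genotypes, Hsd3b5 fell with fasting by -3.70 in wild-type mice, and Saa1 was highest in the ringed mice.

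In fasted mice (3 knockout against 5 wild-type), 70 genes were higher and 37 lower in the knockout, 25 of the 107 by at least 2-fold. Hsd3b5 was higher by 2.74 ± 0.27 (adjusted p = 0.000367) and Hsd3b3 by 2.14 ± 0.22 (adjusted p = 0.000367), again with shared probes in question. The membrane peptidase gene Mme rose by 2.78 ± 0.47 (adjusted p = 0.0122, a lower bound, from a dim mean of 2.36), Sugct by 2.53 ± 0.34 (adjusted p = 0.00311) and the peroxisomal transporter gene Abcd2 by 1.59 ± 0.34 (adjusted p = 0.0476). The fatty acid transporter Cd36 rose by 1.06 ± 0.19 (adjusted p = 0.0178). Obp2a fell by -3.51 ± 0.63 (adjusted p = 0.0169), Cd59a by -1.15 ± 0.16 (adjusted p = 0.00326), Pklr, the liver pyruvate kinase, by -1.05 ± 0.21 (adjusted p = 0.0321) and the malic enzyme gene Me1 by -1.13 ± 0.24 (adjusted p = 0.0441). The other probe set of Me1 gave -1.16 (adjusted p = 0.0867). For all 107 the arrays of the 2 groups did not overlap, which largely follows from calling genes with 3 against 5 arrays.

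Interferon response genes rose in 9 of 39 and fell in none (22 adjusted over the list alone), mean 0.47, adjusted p = 2.79e-21, and adjusted p = 0.147 with an estimated correlation. Ifit1 rose by 1.40 ± 0.24, Bst2 by 1.05 ± 0.15 and Rsad2 by 1.05 ± 0.20, and every knockout fasted mouse scored above every wild-type fasted mouse. Kupffer cell and macrophage markers rose in 1 of 34, Clec4f at 0.54 ± 0.12 (5 adjusted over the list alone; mean 0.24, adjusted p = 3.45e-09, and adjusted p = 0.292 with an estimated correlation). Male-biased genes rose in 2 of 22, Hsd3b5 and the anion transporter gene Slco1a1 at 0.68 ± 0.14 (9 up and 1 down adjusted over the list alone; mean 0.46, adjusted p = 7.57e-10, and adjusted p = 0.292 with an estimated correlation). Endoplasmic reticulum and heat shock stress genes rose in 1 of 35, Pdia6 at 0.91 ± 0.12 (9 adjusted over the list alone; mean 0.29, adjusted p = 8.12e-09, and adjusted p = 0.679 with an estimated correlation). In the fit without knockout fed mice 1 and 4, which are not among the mice compared here, 10 of the 35 rose, with adjusted p = 0.0183 with an estimated correlation. Mitochondrial fatty acid oxidation fell in 2 of 25, Acadm at -0.45 ± 0.08 and Hadh at -0.40 ± 0.07 (1 up and 2 down adjusted over the list alone; mean -0.13, adjusted p = 0.00136, and adjusted p = 0.752 with an estimated correlation). Without wild-type fasted mouse 1 the mean was -0.07 (adjusted p = 0.163).

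Complement and coagulation genes had 1 rise and 1 fall of 43, F11 at 0.66 ± 0.14 and Cd59a, with a mean of 0.11 (adjusted p = 0.000125, and adjusted p = 0.679 with an estimated correlation). Stellate cell markers (none of 26 passed, mean 0.17, adjusted p = 0.00136) and sinusoidal endothelial markers (1 of 24 rose, Cd36, mean 0.14, adjusted p = 0.00352) both had adjusted p = 0.679 with an estimated correlation, and the stellate mean was 0.085 without knockout fasted mouse 1 (adjusted p = 0.0592). Pancreas markers had a mean of -0.45 with none of 17 passing (adjusted p = 0.000572, and adjusted p = 0.752 with an estimated correlation), and of -0.12 without wild-type fasted mouse 5 (adjusted p = 0.0277). Among the arrays of this comparison, the removal of knockout fasted mouse 2 or 3 lowered the count to 22 or 21, and array weights raised it to 185.

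Averaged over both feeding states, the knockout changed 309 genes, 192 up and 117 down, 33 of them at least 2-fold. Interferon genes were higher again, with Ifit1 at 1.33 ± 0.17 (adjusted p = 0.000635), Gbp3 at 1.26 ± 0.15 (adjusted p = 0.000424), Rtp4 at 1.13 ± 0.11 (adjusted p = 0.000151) and the interferon regulatory factor gene Irf7 at 1.13 ± 0.18 (adjusted p = 0.00326). Hsd3b3 rose by 1.89 ± 0.16 (adjusted p = 2.27e-05) and the selenium-binding protein gene Selenbp2 by 1.33 ± 0.23 (adjusted p = 0.00509). Asic5 fell by -2.21 ± 0.35 (adjusted p = 0.00313), Cd59a by -1.11 ± 0.11 (adjusted p = 0.000151), the thiopurine methyltransferase gene Tpmt by -1.11 ± 0.13 (adjusted p = 0.000468), Nmrk1 by -0.87 ± 0.09 (adjusted p = 0.00018) and the mitochondrial deacylase gene Sirt5 by -0.75 ± 0.10 (adjusted p = 0.000836).

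Of 39 interferon response genes, 25 rose and none fell (29 adjusted over the list alone), mean 0.60, adjusted p = 4.61e-49, and 0.00607 with an estimated correlation. Of 34 Kupffer cell and macrophage markers, 13 rose and none fell (22 up and 2 down adjusted over the list alone), mean 0.34, adjusted p = 8.95e-25, and 0.0192 with an estimated correlation; Mpeg1 rose by 1.10 ± 0.17, Clec4f by 0.71 ± 0.08 and the protease gene Ctsc by 0.61 ± 0.10. Without knockout fed mice 1 and 4 the list means were 0.58 and 0.34, with 23 and 8 genes up, and both held with an estimated correlation (adjusted p = 0.0176 and adjusted p = 0.0355). Endoplasmic reticulum and heat shock stress genes rose in 5 of 35 (19 adjusted over the list alone; mean 0.36, adjusted p = 9.31e-18, and adjusted p = 0.184 with an estimated correlation), such as the chaperone Hyou1 at 0.84 ± 0.17; without those mice the mean was 0.17, with adjusted p = 0.0355 with an estimated correlation. Mitochondrial fatty acid oxidation fell in 2 of 25 genes (4 adjusted over the list alone; mean -0.11, adjusted p = 5.97e-05, and adjusted p = 0.626 with an estimated correlation), Acadm at -0.42 ± 0.05 and Hadh at -0.35 ± 0.05.

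Acute phase genes rose in 1 of 38, Crp at 0.42 ± 0.09, with a mean of 0.37 (adjusted p = 3.86e-09, and adjusted p = 0.609 with an estimated correlation), and the mean was 0.08 without knockout fed mice 1 and 4 (adjusted p = 0.0213). Immediate early genes (none of 27, mean 0.28, adjusted p = 0.00149) had a mean of 0.12 without mouse 1 alone (adjusted p = 0.158). Complement and coagulation (1 up and 1 down of 43, mean 0.06, adjusted p = 0.00269) and T and NK cell markers (none of 24, mean 0.04, adjusted p = 0.0366) were called too; with an estimated correlation these 3 lists each had adjusted p = 0.626. The T and NK call was lost without any of 6 single mice (adjusted p = 0.0629 to 0.12), and the complement mean was 0.04 without knockout fed mice 1 and 4 (adjusted p = 0.0804). Cell cycle genes rose in 1 of 37, Ccnd1 at 0.79 ± 0.15 (mean 0.07, adjusted p = 0.000394, and adjusted p = 0.184 with an estimated correlation). The whole count became 171 without those 2 mice. The test fry, of whether a list moves on balance one way, called 12 lists for fasting in wild-type mice and 9 in knockout mice, where an estimated correlation in camera kept 3 and 6. It called 2 lists for knockout in fed mice, 1 in fasted mice, 2 in the mean and none in the interaction. Across the 6 contrasts, 6 lists were never called by camera. Their smallest adjusted p was 0.175 for pericentral genes, 0.606 for hepatocyte markers, 0.306 for B cell and plasma cell markers, 0.0964 for cholangiocyte markers, 0.672 for red cell markers and 0.167 for adipocyte markers.

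The knockout effects in fed and in fasted mice shared 11 genes up, where 0.316 would be expected by chance, and 5 down, where 0.0835 would be expected, with none opposite. They include Gbp3, Ifit1, Clec4f, Hsd3b3, Cd59a, Tpmt and Acadm, and the comparisons share no array. Of the 135 genes changed in fed mice, 115 (85.2%) had the same sign in fasted mice, and of the 107 changed in fasted mice, 89 (83.2%) had the same sign in fed mice. Across all genes the correlation of log2 changes was r = 0.0524 (across genes, which are not independent replicates). The overlap was 9 genes without knockout fed mice 1 and 4.

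Mice with a targeted gene can keep sequence of the embryonic stem cell strain around it, so the genes near Ppard were compared with the rest. Of the 300 tested neighbours of Ppard, 3 were changed in the mean knockout comparison, against 306 of the 19549 genes placed elsewhere. The odds ratio was 0.635 (95% interval 0.13 to 1.89, Fisher's exact test, two-sided, p = 0.636). In a comparison chosen after the values were seen, the changed genes were uneven over the chromosomes among brighter genes, with 26 of 559 on chromosome 3 and 30 of 664 on chromosome 8 (4.65% and 4.52%, against 2.40% and 2.39% elsewhere; Fisher's exact test, adjusted p = 0.0213 for both).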

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

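The tests of the 3 patterns weighed here (interferon and macrophage genes, chromosomes, and the size of the fasting response) were chosen only after the results were seen; the test of the neighbours of Ppard and the counts over other splits of the arrays were planned.

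Averaged over the 2 feeding states, array scores of interferon response and macrophage genes were higher in knockout mice by 0.601 ± 0.0817 and 0.342 ± 0.059 (exact permutation p = 0.000255 and 0.00128, two-sided, over the 3920 ways to exchange genotypes within a feeding state). Each state alone shows less. The lists had, with an estimated correlation, adjusted p = 0.0214 and adjusted p = 0.0518 in fed mice, and adjusted p = 0.147 and adjusted p = 0.292 in fasted mice, where 1 of 34 macrophage genes passed and the macrophage scores of the genotypes overlapped. The 2 knockout fed mice with high acute phase genes do not account for it, since the interferon mean in fed mice was 0.70 without them against 0.73. A larger share of macrophages alone predicts no larger rise of interferon genes than of macrophage markers, but the interferon score rose by 0.258 ± 0.0766 more (exact permutation p = 0.00255). That prediction needs both lists to follow macrophages equally well. Markers that are dim or also made by other cells lower the macrophage mean. The test therefore cannot exclude a larger share of macrophages, which stays open. A lower share of hepatocytes would raise every other cell type alike, but macrophage markers rose by 0.323 ± 0.0687 over the mean of endothelial, stellate and bile duct markers (exact permutation p = 0.00459), which itself differed by 0.0192 ± 0.047 (p = 0.716, exact). Hepatocyte markers were not called by camera in any contrast (smallest adjusted p = 0.606). This comparison, too, needs the lists to follow their cells equally well, so it cannot fully exclude a lower share of hepatocytes. The genotype, activation of resident macrophages, and any difference in housing, microbes or strain between the genotypes stay open as untested.

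Genes changed in the mean knockout comparison were unevenly spread over the chromosomes among 11925 brighter genes: 4.65% of those on chromosome 3 and 4.52% of those on chromosome 8, against 2.40% and 2.39% elsewhere (odds ratios 1.98 and 1.93, adjusted p = 0.0213 for both, Fisher's exact test over 20 chromosomes). Random placement of the 299 called genes gave a chi-square of 44.5 or more with p = 0.00073 (permutation test, 100000 draws). With the list genes and neighbouring family members left out the permutation p was 4e-05, so those genes alone do not account for it. Chromosomes 3 and 8 were not tested again without them. Unlisted pathways and families that are not adjacent stayed in, and the draws place genes independently. The test therefore cannot exclude pathways and families that sit together, which stay open. Expected counts follow the number of genes per chromosome, so gene density is already allowed for. Highly expressed chromosomes would make as many fasting genes uneven too. The 299 strongest gave permutation p = 0.504 in wild-type and 0.427 in knockout mice. Strain sequence that differs between the knockout and wild-type mice, on a mixed background, may be the source of part of the knockout calls, whether by expression or by probe binding. No genotypes were analysed here, and around Ppard itself, where such sequence would be linked to the targeted gene, the odds ratio was 0.635.

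Fasting changed 732 genes in knockout mice and 1838 in wild-type mice. Fewer fasted arrays do not account for the whole gap, since wild-type mice with 3 of their 5 fasted arrays gave 1121 to 1620 genes over the 10 choices. For 300 genes picked in other wild-type arrays, the knockout change was 0.742 of the held-out wild-type change (0.655 to 0.839 over 60 choices of arrays), and without knockout fed mice 1 and 4 the ratio was 0.679, with a highest value of 0.798. Picking in wild-type mice favours genes that respond more there, and no pick in knockout arrays was made. Genes called in knockout mice had a median wild-type to knockout ratio of 0.78, and genes called in wild-type mice a knockout to wild-type ratio of 0.511. Both are lowered by picking in the arrays measured, unlike 0.742. A ratio under 1 therefore does not by itself show a smaller response in knockout mice. A weaker fast, alike for all genes, would leave lipid synthesis genes falling less in knockout mice, by at least 0.12, but the change of the 51 genes was -0.91 in knockout and -0.72 in wild-type mice, a difference of -0.19 ± 0.12, or 2.67 standard errors below 0.12. The difference was -0.12 ± 0.09 without wild-type fed mouse 4 (2.80 standard errors below the 0.14 then predicted) and -0.12 ± 0.13 without knockout fed mice 1 and 4 (2.08 below 0.15, the smallest gap of all settings). The 51 genes were chosen after the falls of both lists in each genotype had been seen. The predicted value rests on the ratio above and enters without an error. The test therefore cannot decide on a weaker fast, which stays open. A genotype effect on part of the response, and differences in when the mice were killed or last ate, stay open as untested.

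Other splits of the same arrays were counted for each contrast. The real split gave the most genes for knockout in fed mice, 135, against at most 11 in any other of 35 splits. It did so for knockout in fasted mice (107, at most 15 in any other of 56). The same held for fasting in wild-type mice (1838, at most 568 of 100) and in knockout mice (732, at most 453 of 35). It also held for the mean knockout effect (309, at most 2 of 100). In each of these contrasts 1 split, the real one, gave as many. The smallest share such a count can give is 1 in 35, 1 in 56 or 1 in 100. Shares of that size cannot exclude chance when several contrasts are tested, so no conclusion on chance is drawn from them. For the interaction, 2 genes were called and 5 of 100 splits gave as many, with at most 5 genes. Chance is not excluded there either.

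The fasting response differed between genotypes by test for Hsd3b5 (2.72) and Tc2n (0.95), but chance is not excluded for these 2 calls, and neither passed without knockout fed mice 1 and 4 (adjusted p = 0.168 and adjusted p = 0.177). Tc2n was dim in all 4 groups (means 1.92 to 2.51), so 0.95 cannot be taken as the size of a change. It also differed at the preset correlation for 11 lists: PPAR targets (-0.27), amino acid catabolism (0.10), acute phase (-0.90), complement and coagulation (0.11), interferon response (-0.26), male-biased genes (0.77), Kupffer cell and macrophage markers (-0.21), neutrophil markers (-0.38), sinusoidal endothelial markers (0.19), stellate cell markers (0.25) and pancreas markers (-0.55). None of the 11 held with an estimated correlation, and the pancreas value was -0.23 without wild-type fasted mouse 5.

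Single arrays stood far from the rest of their group, by Dixon's ratio of the gap to the group's range, in 19 of 495 groups for the 165 named genes (3.84%) and in 9 of 96 groups for the lists (9.38%); chance gives about 1 in 20. In wild-type fed mice, mouse 3 was highest for Angptl4 (0.908), Gstm3 (0.868) and Ctsc (0.839), and mouse 1 lowest for Pck1 (0.834). In wild-type fasted mice, mouse 1 was highest for C6 (0.818) and Fabp5 (0.871), mouse 2 lowest for Fkbp5 (0.744) and Sqle (0.722), mouse 3 highest for Gbp7 (0.772), and mouse 4 lowest for Hsd3b2 (0.735) and Cfp (0.781). In knockout fed mice, mouse 4 was lowest for Cyp4a10 (0.863), Cyp4a31 (0.922) and Aldh3a2 (0.854), mouse 1 lowest for F11 (0.906) and highest for Nmrk1 (0.842), mouse 2 highest for Gbp3 (0.880) and lowest for Col3a1 (0.932), and mouse 3 highest for Raet1d (0.838). Among list scores of wild-type fed mice, mouse 2 was lowest for interferon response (0.979), mouse 1 lowest for MHC class II (0.852) and male-biased genes (0.854), and mouse 4 lowest for cholesterol biosynthesis (0.850). Among those of wild-type fasted mice, mouse 1 was lowest for bile acid synthesis (0.724), mouse 2 lowest for cholesterol biosynthesis (0.731), mouse 3 highest for interferon response (0.713) and mouse 5 highest for pancreas markers (0.785). Knockout fed mouse 2 was lowest for gluconeogenesis (0.852).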

How the results depend on the processing

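Quantile normalization, centring on the common median, and the median of a gene's probe sets left all 10 summary results within 1.5 times their value, and these 2 scalings moved the median log2 change by -0.0316 to 0.0242. Little else was possible, as the deposited values were already normalized with RMA and 998 of 19935 genes had more than 1 probe set. For the changes that follow the cause was not tested, except that leaving out arrays lowers their number. The count of interaction genes, 2, was 1 with dim genes left out, with all probe sets, with an intensity trend and robust variance, with the replicate block and without knockout fed mice 1 and 4. Array weights gave 185 genes for knockout in fasted mice (107) and 25 shared knockout genes (16). A fit of the 2 groups alone, with fewer arrays, gave 76 genes for knockout in fed mice (135) and 401 for fasting in knockout mice (732). An estimated correlation left 12 list calls of 79. Leaving out knockout fed mice 1 and 4, chosen after seeing the data, gave 51 genes for knockout in fed mice, 218 for fasting in knockout mice, 171 for the mean knockout effect (309), 9 shared knockout genes and 182 shared fasting genes (470). It reversed 1 list, endoplasmic reticulum and heat shock stress in the interaction, from -0.13 to 0.249. Leaving out each array in turn gave 59 to 274 genes for knockout in fed mice (59 without wild-type fed mouse 3, 274 without knockout fed mouse 3, 78 without wild-type fed mouse 1 or 2, 77 without mouse 4, 76 and 81 without knockout fed mouse 1 or 4). It gave 21 to 126 for knockout in fasted mice (56, 22 and 21 without knockout fasted mouse 1, 2 or 3, and 70 and 67 without wild-type fasted mouse 4 or 5), and 1199 to 2006 for fasting in wild-type mice (1199 without wild-type fed mouse 3). Fasting in knockout mice ranged from 330 to 951 (418, 330 and 374 without knockout fasted mouse 1, 2 or 3, and 480 without knockout fed mouse 1). The interaction ranged from 0 to 8, and the mean knockout effect from 175 to 359 (182 and 175 without knockout fasted mouse 2 or 3). Shared knockout genes ranged from 5 to 25 (10 without wild-type fed mouse 3, 25 without knockout fed mouse 2, 7 and 5 without knockout fasted mouse 2 or 3), and shared fasting genes from 250 to 515 (305, 250 and 280 without knockout fasted mouse 1, 2 or 3). The Ppard odds ratio stayed between 0.50 and 1.17 and the list calls between 73 and 90. The share of higher genes for knockout in fed mice, 66.7%, was 78.0% without knockout fed mouse 2, 46.0% without mouse 3 and 78.4% without mice 1 and 4, and for fasting in knockout mice, 51.0%, it was 39.4% without knockout fed mouse 2. Replicate numbers do not pair the mice: residuals of arrays with the same number correlated across genes with a mean r of 0.035 (-0.224 to 0.208, 21 pairs), against -0.009 for different numbers, and 4 of 16 arrays had their best partner under their own number. As a replicate block the number gave 170, 73, 1656, 745, 1 and 315 genes in the order fed knockout, fasted knockout, wild-type fasting, knockout fasting, interaction and mean knockout, and 52.1% higher genes for knockout in fasted mice (65.4%). Dim genes lie near the background of the arrays, where small differences cannot be seen.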

Other observations

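The naming rule gave Dbp, Per1 and Arntl for fasting in wild-type mice and Per1 for fasting in knockout mice. Their other values here, and Per3 and Clock, were chosen after the values were seen, while the list test was planned; no explanation was tested. No circadian clock gene passed between the genotypes in fasted mice. Knockout minus wild-type in fasted mice was -1.49 ± 0.43 for Dbp (adjusted p = 0.177) and -1.03 ± 0.24 for Per3 (adjusted p = 0.0621), and 0.61 ± 0.20 for Arntl (adjusted p = 0.262) and 0.35 ± 0.10 for Clock (adjusted p = 0.187). Fasting changed Per1 by 1.94 ± 0.16 in wild-type mice and by 0.81 ± 0.19 in knockout mice, with an interaction of -1.13 ± 0.25 (adjusted p = 0.15). For Dbp the interaction was -1.88 ± 0.60 (adjusted p = 0.271). The list of 21 clock genes had a mean of -0.25 in fasted mice (adjusted p = 0.0519), with 5 lower and 2 higher adjusted over the list alone.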
